A study of Mus musculus with 28 samples.

How the data were processed

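RNA sequencing libraries were made from mouse embryonic cortex at embryonic day 14.5 (E14.5) and from adult prefrontal cortex (PFC) of a line with a knocked-out Myt1l gene. Per the labels' protocols, total RNA was extracted with a Zymo kit and libraries were prepared with the SMARTer Ultra Low RNA kit. Per the submitters' processing notes, Trimmomatic, Bowtie2, STAR and HTSeq were used with the mouse genome build mm10. Their versions and roles are not given in the sources used here. Whether reads were counted by strand is not given either, so reads of overlapping, antisense or near-identical genes cannot be told apart.

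The authors deposited 1 table per tissue, named as CPM (read counts scaled to a common library total) after RUVr, a method that estimates unwanted variation from the residuals of a first fit and removes it. The deposited values are log2 CPM with a prior count of 2. This was read from the values: each library has the same lowest value and the same upper quartile, and the steps between low values invert to whole numbers. With a tolerance of 0.01, 100% of the values in both tables came out whole. These whole numbers had been scaled to a common upper quartile and adjusted by RUVr, so they are not raw read counts and the sequencing depth of each library is unknown. Their totals ran from 27827467 to 30811856 per E14.5 library and from 19601294 to 21275162 per PFC library. A step of 1 was worth 0.0339 CPM in the E14.5 table and 0.0489 CPM in the PFC table, and 3 such steps, the floor used for a gene at 0, were worth 0.102 and 0.147 CPM. Floors cover counting error only.

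The adjustment left traces in the values. Over 8550 genes of the E14.5 table with a mean number over 200, 2 directions among the 16 libraries held almost no variance, with a singular value of at most 0.0568 against at least 10.3 for the others. Likewise, 1 such direction was found among the 12 PFC libraries. These directions use up degrees of freedom that a test on the table does not count. They were therefore added as covariates in an alternative fit, which counts these directions but cannot undo other effects of the step.

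There were 13846 genes listed for E14.5 and 14104 for the PFC, of which 13840 and 14098 matched an Ensembl identifier of the mouse annotation GENCODE vM21 on GRCm38, the assembly that mm10 also names. Coordinates, gene types, GC content and length of the longest transcript came from that annotation. Genes with at least 1 CPM in at least 4 libraries (E14.5) or 6 libraries (PFC) were tested, which kept 12429 and 12870 genes. CPM was recovered from the log2 values, and log2(CPM + 0.5) was analysed with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust). A fold change on this scale understates the change of genes with low CPM. Genotype and sex as labelled were the covariates, all libraries of a tissue entered 1 fit, and p-values were adjusted by the Benjamini-Hochberg method. A gene is described as called, higher or lower when its adjusted p was under 0.05. Figures were drawn with matplotlib 3.10.9.

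The comparisons were homozygous (Hom) and heterozygous (Het) mutants against wild type (WT) at E14.5, Hom against Het, a slope over the number of Myt1l copies lost, Het against WT in the PFC, and the interaction of genotype and sex in the PFC. The agreement of fold changes between comparisons was measured by Pearson's r across genes, which are not independent replicates. It was set against 100 permutations of PFC genotype labels within sex, or against simulated unchanged groups where WT libraries were shared. In these simulations, residuals were first drawn over all libraries and later within each genotype. That change was made after the first values had been seen, and both versions are given.

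Gene lists were fixed before the data were examined: 26 lists of progenitor, cell cycle, neuronal, synaptic, pathway, glial, vascular and other cell type genes. Lists with at least 3 tested genes were compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The list of sex-linked genes served only to check labels. Named genes followed a rule fixed before the data were examined: Myt1l and its family members Myt1 and St18, the 10 largest rises and 10 largest falls among called genes with every mutant library on the same side of the WT mean, and up to 4 members of each list with the lowest p. Genes chosen outside that rule are marked as such, and some genes that met it are not reported here.

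Each test was tried on simulated numbers with 200 genes changed by known folds. At a 1.4-fold change, 92% of changed genes were recovered for Hom against WT over 12090 simulated genes, 94% for Het against WT over 12093 genes, 84% for Hom against Het over 12094 genes and 97% for the PFC comparison over 12771 genes. The interaction with sex recovered 16% at 1.4-fold and 93% at 2-fold over 12778 genes. These simulations held no unwanted variation. They gave all genes of a tissue the same dispersion (0.011 at E14.5 and 0.00927 in the PFC), and 100 of the 200 changed genes changed by 2-fold. The shares therefore do not measure recovery in the real libraries, where genes differ in spread. A second set without any genotype effect was put through an RUVr step, with loadings of unwanted variation of 3 sizes. As such a step can raise the number of calls without any effect, counts and p-values from both tables may be too optimistic. Adding the removed directions as covariates did not end this. With loadings of 0.2 (SD, log2) that fit gave medians of 883 calls (Hom against WT), 643 (Het against WT), 400.5 (Hom against Het) and 439.5 (PFC).

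Alternatives covered the pseudocount, the filter, scaling, covariates, the libraries used, the removed directions, the eBayes settings, the threshold and leaving out each library in turn. The planned edgeR test was not run, since the recovered numbers are not raw counts, and limma voom on these numbers took its place. Added after the data had been examined were voom, the log2 values as deposited, exchanged sex labels, a correction for GC content and length, fits within 1 sex in the PFC, and lists of glycolytic and ribosomal genes. Replicates were compared within groups: the root mean square difference of each pair was 3.08 to 8.71 times the noise of counts as large as the recovered numbers. As these are not raw counts, the ratio ranks the pairs and does not measure technical noise. The prefix of the sample identifier, which several animals share, was tried as a block. Chromatin accessibility data of the same study were not analysed here, and Xist is not analysed here.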

Results

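The series measured gene expression by RNA sequencing in a mouse line with a knocked-out Myt1l gene, which encodes a zinc-finger transcription factor of neurons. The stated purpose was to find how the transcriptome changes when MYT1L is lost, in the developing cortex and in the adult PFC. The 28 libraries comprised 6 WT, 6 Het and 4 Hom libraries of E14.5 cortex and 6 WT and 6 Het libraries of adult PFC. Each library carries its own animal identifier. By label, 5 of 6 WT, 3 of 6 Het and 3 of 4 Hom embryos were female, and each PFC group held 3 females and 3 males. Recovered totals lay between 27827467 and 30811856 per E14.5 library and between 19601294 and 21275162 per PFC library. They follow the authors' scaling and are not sequencing depths, which are unknown.

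Myt1l was lower in Hom embryos, at 36.4% of the WT mean, and in the PFC of Het adults. The gene (ENSMUSG00000061911) is protein coding and spans chromosome 12 from 29528384 to 29923213 on the plus strand of GRCm38. In E14.5 cortex it measured 55.5 CPM ± 8.16 (SD, n = 6) in WT, 42.8 CPM ± 11.1 (SD, n = 6) in Het and 20.2 CPM ± 2.35 (SD, n = 4) in Hom. The Hom libraries ran from 18.2 to 23.3 CPM, below each WT library (45.9 to 66.6 CPM), and the log2 change was -1.43 (SE 0.16, limma adjusted p = 1.1e-04). The Het change of -0.39 (SE 0.15) did not pass the test (adjusted p = 0.125), although 5 of 6 Het libraries lay below the WT mean. The exception was the library labelled Het F02, at 59.5 CPM. It lay within the WT range, as did Het M07 at 48.9 CPM and Het F07 at 45.95 CPM. In adult PFC, Myt1l measured 158 CPM ± 8.48 (SD, n = 6) in WT and 114 CPM ± 6.70 (SD, n = 6) in Het, with each Het library below each WT library (log2 change -0.47, SE 0.06, adjusted p = 1.4e-04). The family members Myt1 and St18 were not called in any of these comparisons. At E14.5, Myt1 measured 34.0 CPM ± 2.98 (SD, n = 6) in WT and 34.6 CPM ± 3.29 (SD, n = 4) in Hom. Y-linked genes matched the labelled sex in all libraries except a pair of Het embryos: Ddx3y was at 21.6 CPM in the library labelled Het F10 and at 0 in the library labelled Het M11.

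**Figure D1:**
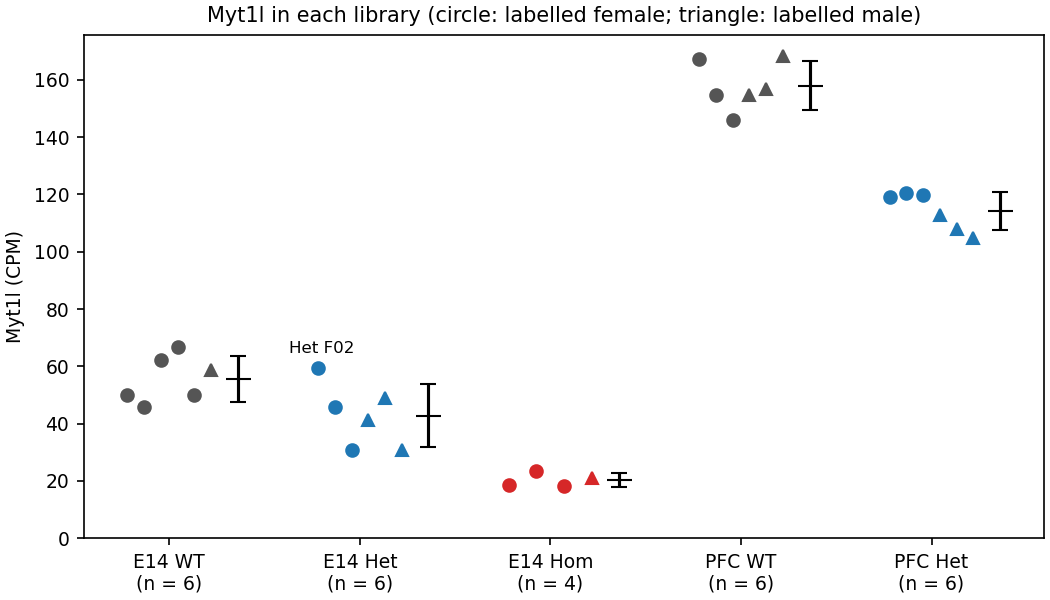
Myt1l in CPM (y axis) in each library of the 5 groups (x axis), circles for libraries labelled female, triangles for male; black bars give the mean ± SD. The 4 Hom libraries lie between 18.2 and 23.3 CPM, and the library labelled Het F02 reaches 59.5 CPM.

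In Hom embryos, 5 of 22 S phase genes were lower and 2 of 12 GABAergic interneuron genes higher than in WT, and with an estimated correlation neither list passed (adjusted p = 0.617 and 0.753). Of 12429 genes tested, 944 were called, 401 higher and 543 lower, most by little: 234 changed by more than 0.5 on the log2 scale and 13 by more than 1. Subunits of the MCM helicase, which unwinds DNA at replication origins, were among the clearest falls. Mcm5 (chromosome 8, 75109569 to 75128439) went from 276 CPM ± 36.5 to 183 CPM ± 4.60 (SD, n = 6 and 4), a log2 change of -0.59 (SE 0.10, adjusted p = 0.00216), and Mcm7 changed by -0.51 (SE 0.08). Sp9, a transcription factor of interneuron precursors, rose by 1.26 (SE 0.28, adjusted p = 0.00811) in Hom. Basp1, a membrane protein of growth cones, rose by 0.64 (SE 0.11), from 116 to 183 CPM.

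Among the largest rises by the naming rule were Pou4f1, a transcription factor of sensory neurons (1.51, SE 0.38), Lox, which cross-links collagen and elastin (1.42, SE 0.34), and Depdc7 (1.18, SE 0.26). Cd36, a fatty acid receptor, rose by 1.16, Rfx1 by 1.08, Vsir by 1.05 and Ngfr, a neurotrophin receptor, by 0.92. Most of these genes are weakly expressed: Depdc7 averaged 0.301 CPM in WT and 1.36 CPM in Hom, and Pou4f1 0.516 CPM ± 0.276 and 3.13 CPM ± 3.11 (SD, n = 6 and 4). Among the largest falls after Myt1l were Tlr12 (-1.24, SE 0.29), Ablim3, an actin-binding protein (-1.20, SE 0.26), Aldh1l2, an enzyme of mitochondrial folate metabolism (-1.01, SE 0.21), and Fer1l5 (-0.99, SE 0.22). Pdgfb, a growth factor, fell by 0.94 on the log2 scale and Il1rap, a receptor subunit of interleukin signalling, by 0.95.

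Of the cell cycle lists, the S phase list had 5 of 22 genes lower and none higher (5 adjusted over the list alone), among them Mcm3 (-0.41) and Cdc6, which licenses replication origins (-0.51). The G2 and mitosis list had 3 of 24 genes lower (3 adjusted over the list alone), including the mitotic kinase Aurka (-0.44, SE 0.08) and the cyclin Ccnb1 (-0.24, SE 0.07). Ccnb1 stood high in WT F04 (502 CPM), a library that the Het comparison also uses. Its Hom call was lost under another pseudocount, filter, scaling or the GC correction. Both lists were lower than other genes by camera with the preset correlation (adjusted p = 0.00153 and 0.0211), but not with an estimated correlation (adjusted p = 0.617 and 0.753). The GABAergic interneuron list had 2 of 12 genes higher (2 adjusted over the list alone), Sp9 and Dlx1 (0.89, SE 0.23), with a median log2 change of 0.47. Its camera adjusted p was 0.0419, and 0.753 with an estimated correlation. Markers of ventral telencephalon and striatum stood high in some of the same libraries: Isl1 measured 16.4 CPM in Hom F01, 15.95 CPM in Hom M02 and 12.7 CPM in Het M07, against at most 5.11 CPM in WT. Of that list, 1 of 8 genes was called, Ppp1r1b, a phosphoprotein of striatal neurons (0.72, SE 0.20).

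Neuronal lists held single calls in both directions. The early neuronal differentiation list had 2 genes higher and 1 lower of 20 (4 and 1 adjusted over the list alone), with Nefm, a neurofilament subunit, at 0.78 (SE 0.21), Tbr1, a transcription factor of deep-layer neurons, at 0.45 (SE 0.13) and the neuronal tubulin Tubb3 at -0.26 (SE 0.06). The immature neuron list had 3 of 20 genes higher, Basp1, Marcksl1 (0.40, SE 0.11) and Tmsb10 (0.36, SE 0.10), and Tubb3 lower (5 and 1 adjusted over the list alone). In the radial glia list, Sox2, a transcription factor of neural progenitors, rose by 0.59 (SE 0.14), whereas the membrane protein Prom1 fell by 0.43 on the log2 scale. The upper-layer list had Pou3f1 higher (0.68, SE 0.20) among 10 genes and the deep-layer list Tbr1 (2 and 4 adjusted over the list alone). The synaptic lists held falls of Sv2a, a synaptic vesicle protein (-0.58, SE 0.14), and Shank1, a postsynaptic scaffold (-0.56, SE 0.16), while 19 of 20 presynaptic and 15 of 16 postsynaptic genes were not called. Numb, an inhibitor of Notch signalling, was lower (-0.50, SE 0.14) among 15 Notch pathway genes, and Mfap4 (-0.28, SE 0.07) among 11 intermediate progenitor genes. The astrocyte list held a fall of Aldoc, a glycolytic aldolase (-0.42, SE 0.07), among 8 genes.

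Lists that report on other cells and on RNA quality also moved. The erythroid list was lower by camera (median -0.30, adjusted p = 0.0477), and 0.753 was its adjusted p with an estimated correlation. The mitochondrially encoded list was higher (median 0.22, adjusted p = 0.0211, and 0.753 as adjusted p with an estimated correlation), with 1 of 9 genes called, mt-Co3 (0.35, SE 0.10). Correction for GC content and length ended that call (adjusted p = 0.533). No gene was called in the Wnt, choroid plexus, endothelial, immediate early, meningeal, microglial, oligodendrocyte or ion channel lists, whose camera adjusted p-values were 0.131 or higher. The list of Myt1l and its family was also lower by camera (adjusted p = 0.0419, and 0.525 as adjusted p with an estimated correlation), through Myt1l itself.

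The count of 944 fell to 511 with the removed RUVr directions as covariates, to 468 without the trend and robust settings, and to between 489 and 592 when Hom F01, Hom F04, Hom F09, Hom M02 or WT F04 was left out. The split of 401 higher and 543 lower became 294 and 746 with each library centred on its median, and 231 and 553 after correction for GC content and length. Of the 44 named genes called, 13 stayed called wherever they were tested among the other pseudocounts, filters and scalings, GC correction and fits without any single library. These were Ablim3, Aldh1l2, Aldoc, Aurka, Basp1, Cdc6, Depdc7, Fer1l5, Mcm3, Mcm5, Mcm7, Myt1l and Sp9. A gene that a filter removed was not tested with it, such as Sp9 and Depdc7 with the filter of 5 CPM. This set of alternatives leaves out changed covariates and eBayes settings.

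**Figure D2:**
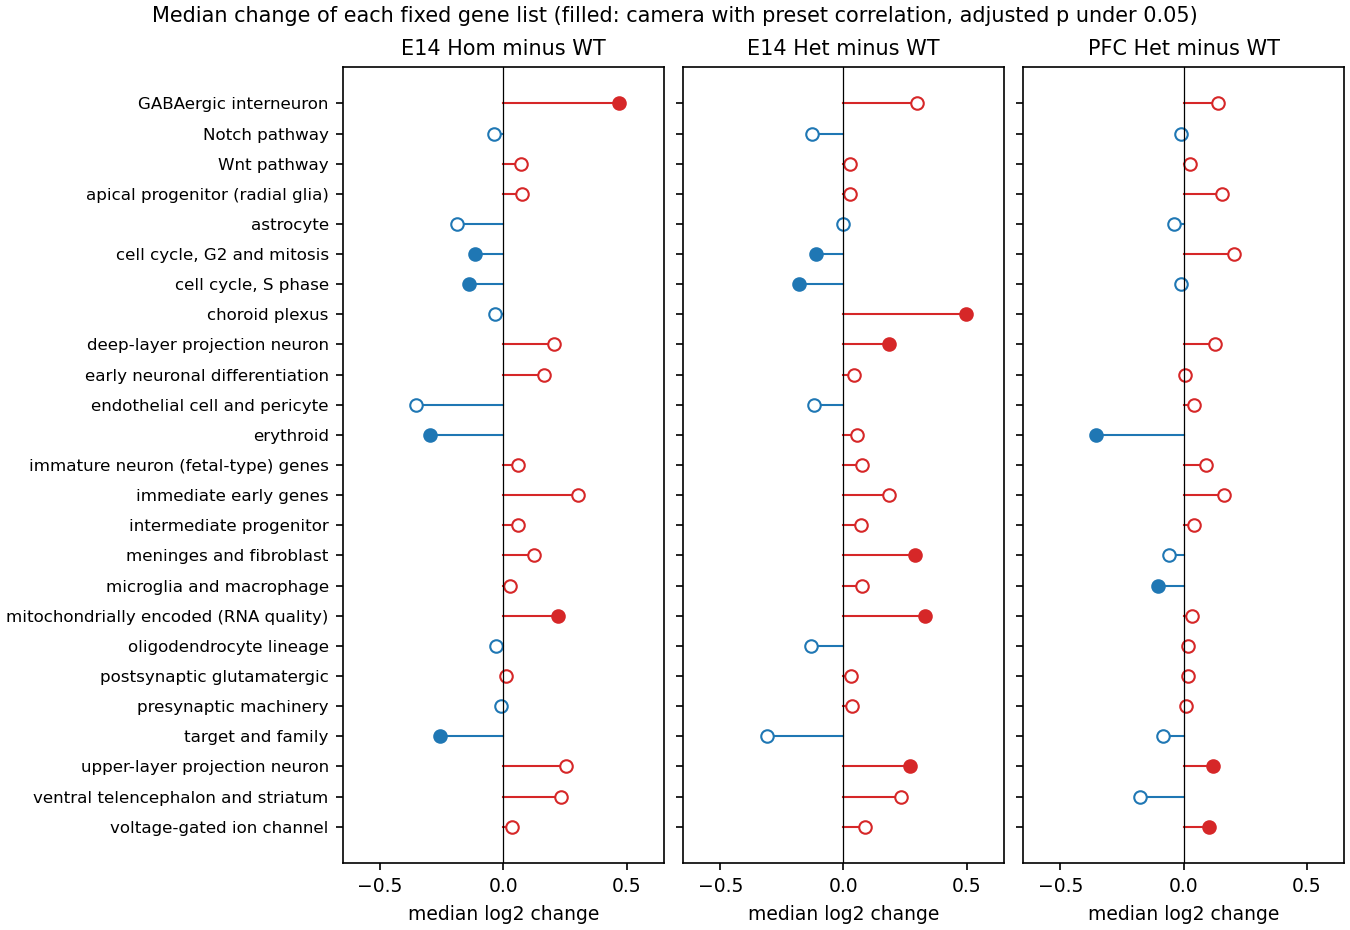
Median log2 change (x axis) of the tested genes of each fixed list (y axis) in the 3 comparisons with WT; filled circles mark a camera adjusted p under 0.05 with the preset correlation, red a median above 0 and blue below. In Hom the GABAergic interneuron list lies at 0.47 and the S phase list at -0.14, and neither call held with an estimated correlation.

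In Het embryos, 4 of 22 S phase genes were lower and 3 of 10 upper-layer genes higher than in WT, and with an estimated correlation neither list passed (adjusted p = 0.430 for both). Among 12429 genes, 724 were called, 353 higher and 371 lower, of which 145 changed by more than 0.5 on the log2 scale. Mcm5 went from 276 CPM ± 36.5 to 194 CPM ± 32.5 (SD, n = 6 and 6), a log2 change of -0.56 (SE 0.09, adjusted p = 0.00319). Mcm7 changed by -0.47, Mcm3 by -0.42 and Rrm1, a subunit of ribonucleotide reductase, by -0.38. Tbr1 rose from 34.4 to 48.7 CPM (0.55, SE 0.12).

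The S phase list had 4 of 22 genes lower (8 adjusted over the list alone; camera adjusted p = 1.7e-05) and the G2 and mitosis list 4 of 24 (6 adjusted over the list alone; camera adjusted p = 8.6e-04), among them Aurka (-0.31), Tpx2 (-0.27) and Ccnb1 (-0.25). With an estimated correlation their adjusted p-values were 0.430 and 0.608. The upper-layer list had 3 of 10 genes higher (3 adjusted over the list alone), among them Pou3f2 (0.36, SE 0.08) and the netrin receptor Unc5d (0.48, SE 0.14), and passed by camera (adjusted p = 0.0147, and 0.430 as adjusted p with an estimated correlation). The deep-layer list passed with 1 of 10 genes called, Tbr1 (1 adjusted over the list alone; adjusted p = 0.0369, and 0.430 as adjusted p with an estimated correlation). Tbr1 and Neurod6, a transcription factor of differentiating projection neurons (0.24, SE 0.07), were higher and Tubb3 (-0.23, SE 0.06) lower in the early differentiation list. Basp1 (0.53, SE 0.10) and Tmsb10 (0.40, SE 0.10) were higher in the immature neuron list, Aldoc (-0.39, SE 0.07) was lower in the astrocyte list, and the proneural factor Neurog2 (0.36, SE 0.09) was higher in the intermediate progenitor list.

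Markers of tissue next to the cortex and of RNA quality moved as well. The choroid plexus list was higher by camera (median 0.50, adjusted p = 0.0315, and 0.746 as adjusted p with an estimated correlation) with no gene called: Ttr, the main choroid plexus transcript, measured 2441 CPM ± 908 in WT and 3861 CPM ± 876 in Het (SD, n = 6 and 6; adjusted p = 0.140). The meningeal and fibroblast list was higher (median 0.29, adjusted p = 0.0315, and 0.838 as adjusted p with an estimated correlation), with 1 of 11 genes called, Ogn, a small matrix proteoglycan (0.76, SE 0.19). The mitochondrially encoded list was higher (median 0.33, adjusted p = 2.3e-05, and 0.484 as adjusted p with an estimated correlation), with mt-Co3 (0.53, SE 0.10) and mt-Co2 (0.48, SE 0.14) called. After correction for GC content and length none of these 3 genes was called, nor was the mitochondrially encoded list (adjusted p = 0.148).

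The largest rises were Depdc7 (1.12, SE 0.24), Lox (1.15, SE 0.32), Defb11 (1.05, SE 0.23) and Ppp3cc, a calcineurin subunit (1.02, SE 0.26). The largest falls were Gramd2 (-1.18, SE 0.33), Eda, a signalling ligand of the ectoderm (-1.04, SE 0.25), Camk2a, a calmodulin-dependent kinase (-0.97, SE 0.22), Bak1, an apoptosis effector (-0.97, SE 0.25), and Slc2a5, a fructose transporter (-0.90, SE 0.22). Wnt pathway genes had 1 call of 21, the repressor Tcf7l1 (-0.52, SE 0.14), and the 12 GABAergic genes had none (median 0.30, camera adjusted p above the threshold).

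The count of 724 became 335 with the removed RUVr directions as covariates, 225 without the trend and robust settings, 379 when only Het and WT libraries were fitted, and 450 in libraries labelled female, which include Het F10 with its Y-linked transcripts and leave out Het M11. Without Het F07 it was 131, without WT F04 303, without the library labelled Het F02 404, without Het M01 433, without WT F06 440, without WT F12 468, without Hom M02 473 and without Het M07 1177; the split of 353 and 371 became 213 and 509 with median centring and 112 and 383 with correction for GC content and length. Of the 42 named genes called, 8 stayed called wherever they were tested in the same set of alternatives (Aldoc, Basp1, Camk2a, Depdc7, Mcm3, Mcm5, Mcm7 and Rrm1). After the GC correction 17 were not called, among them Lox, Defb11 and Tmsb10. Depdc7, removed by the filter of 5 CPM, was not tested with it, and the set leaves out changed covariates and eBayes settings.

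The Hom and Het changes ran in the same direction for the genes called in both. Of the called genes, 187 were higher and 256 lower in both genotypes, where independent lists of these sizes would share 11.4 and 16.2, and none went opposite ways. Between Hom and Het, 1 of 12429 genes was called, Myt1l itself (-1.04, SE 0.16, adjusted p = 0.0382). Ogn, at -0.75 (SE 0.21), was not called (limma adjusted p = 0.775), so changes of that size could be missed. At an unadjusted p under 0.05 there were 636 genes. The erythroid (median -0.36) and choroid plexus (median -0.58) lists were lower in Hom than in Het by camera (adjusted p = 1.5e-04 and 2.5e-04), neither with an estimated correlation (adjusted p = 0.678 for both) and with no gene called. The Myt1l call was lost with voom, with the identifier prefix as a block, when only Hom and Het were fitted, in libraries labelled female, with the removed directions as covariates, without the trend and robust settings and after correction for GC content and length. It was also lost when any of Hom F01, Hom F04, Hom F09, Hom M02, Het M01, Het M07, Het F07, WT F04, WT F06, WT F12 or WT M03 was left out.

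Both comparisons share the 6 WT libraries, which alone makes their fold changes correlate. Pearson's r across the 12429 genes was 0.682 and the covariance 0.0421. Simulated unchanged groups against the same WT libraries gave a mean r of 0.428 (range -0.0532 to 0.874) and a mean covariance of 0.0123 (highest 0.0267 of 100), a difference in covariance of 0.0299. In the first version of the simulation, which could place 1 residual in both arms, the mean covariance was 0.0147, the highest was 0.0624 and 1 of 100 was as large as the observed one. With the WT libraries divided 3 and 3, so that none was shared, r averaged 0.416 over 20 divisions (0.304 to 0.587) and the covariance 0.0304 (0.0243 to 0.0386), where simulated unchanged groups with divided WT libraries reached an r of 0.754 and a covariance of 0.0245 (0.0335 in the first version).

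A slope over the number of Myt1l copies lost was called for 997 genes, 429 rising and 568 falling. A single step from WT to both mutants also gives such a slope, and 1 gene was called between Hom and Het. The slope calls therefore do not show a change graded by copy number. Per copy, Hdac6, a cytoplasmic deacetylase, changed by -0.32 (SE 0.05), whereas Cdkn1b, an inhibitor of cyclin-dependent kinases, rose by 0.47 (SE 0.13) and Ttc32 by 0.43 (SE 0.10). Hdac6 averaged 69.7 CPM in WT, 49.7 CPM in Het and 45.7 CPM in Hom. Dlx1 rose by 0.45 per copy (11.7, 19.0 and 23.8 CPM), but its Hom libraries differed: 37.6 CPM in Hom F01 and 27.5 CPM in Hom M02, which also had high Isl1, against 16.5 CPM in Hom F04 and 13.7 CPM in Hom F09, the last within the WT range (up to 15.6 CPM). The count was 510 with the removed directions as covariates, 484 without the trend and robust settings, 455 without WT F04, 526 without WT M03, 618 without WT F12, 626 without WT F06 and 659 without Hom F04. Its split became 304 and 746 with median centring and 263 and 566 after correction for GC content and length.

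**Figure D3:**
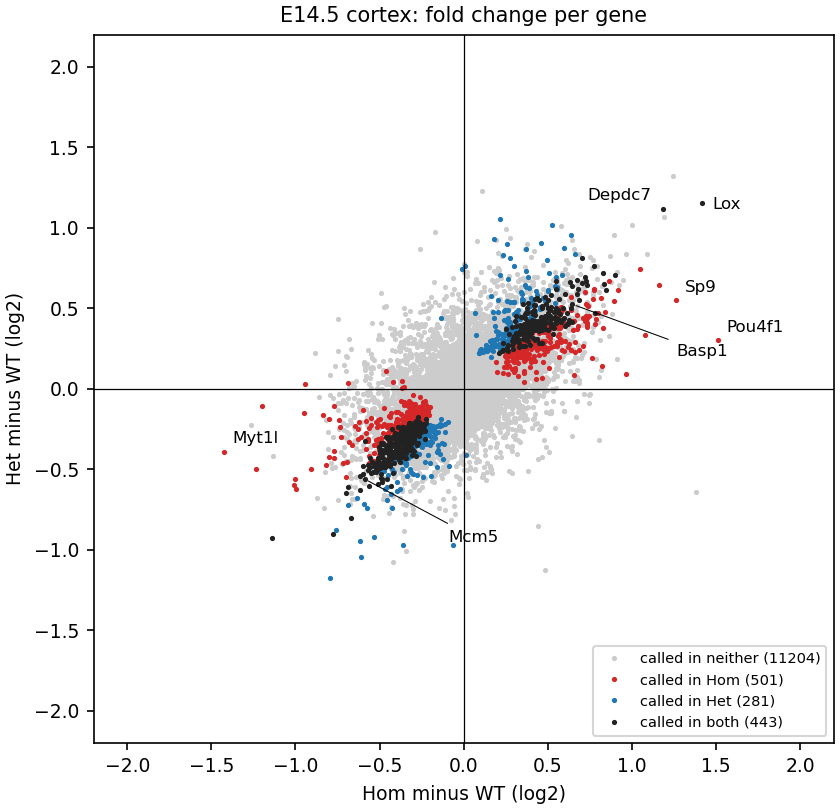
Log2 change of each of 12429 genes in Hom (x axis) and Het (y axis) against the same WT libraries at E14.5; black points are the 443 genes called in both, red 501 in Hom alone and blue 281 in Het alone. Myt1l lies at -1.43 in Hom and -0.39 in Het, and Mcm5 at -0.59 and -0.56.

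In adult PFC, 52 of 12870 genes were called between Het and WT, 23 higher and 29 lower. Besides Myt1l, the clearest fall was Syt3, a synaptotagmin of neuronal membranes (chromosome 7, 44384102 to 44400187), from 45.7 CPM ± 4.01 to 31.5 CPM ± 5.17 (SD, n = 6 and 6; log2 change -0.54, SE 0.09, adjusted p = 0.00685). Tshz1, a zinc-finger transcription factor, rose from 9.62 to 18.1 CPM (0.82, SE 0.15), and Sox11, a transcription factor of immature neurons, from 33.6 to 46.1 CPM (0.44, SE 0.09, adjusted p = 0.0426). Grin1, the obligatory subunit of NMDA receptors, fell by 0.38 on the log2 scale (SE 0.08, adjusted p = 0.0439), from 60.0 to 46.3 CPM. Neither Sox11 nor Grin1 stayed called under all other pseudocounts, filters and scalings and the GC correction.

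Further rises were Prr12 (0.70, SE 0.16), Fosl2, a subunit of the AP-1 transcription factor (0.59, SE 0.12), Ccn4, a secreted matrix protein (0.64, SE 0.14), and Btg1, an inhibitor of proliferation (0.45, SE 0.09). Further falls were Socs3, an inhibitor of cytokine signalling (-1.03, SE 0.20), Zfp575 (-0.81, SE 0.18), Gtf3a, a factor for transcription of ribosomal RNA genes (-0.73, SE 0.13), Dyrk1b, a kinase (-0.69, SE 0.15), and Rac3, a small GTPase (-0.57, SE 0.12). The immature neuron list had 1 of 17 genes higher, Sox11 (1 higher and 2 lower adjusted over the list alone). Marcksl1 of that list measured 44.4 CPM in WT and 34.5 CPM in Het (-0.37, SE 0.09, adjusted p = 0.0507).

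The voltage-gated ion channel list was higher by camera (median 0.10, adjusted p = 0.00244, and 0.565 as adjusted p with an estimated correlation) with none of 22 genes called (2 adjusted over the list alone). The upper-layer list was higher (median 0.12, adjusted p = 0.0235, and 0.450 as adjusted p with an estimated correlation) with none of 10 genes called (2 adjusted over the list alone), the nearest being Cux2 at 0.43 (SE 0.10, adjusted p = 0.0507). The erythroid list was lower (median -0.36, adjusted p = 2.5e-05, and 0.450 as adjusted p with an estimated correlation), with the globin gene Hbb-bt called (-0.54, SE 0.11; 4 of 5 adjusted over the list alone). The microglial list was lower (median -0.10, adjusted p = 0.00720, and 0.565 as adjusted p with an estimated correlation) with none of 12 genes called. The other lists did not pass, the lowest adjusted p being 0.0717 for the deep-layer list. Hes5 of the Notch and radial glia lists measured 15.1 CPM ± 8.82 in WT and 6.75 CPM ± 3.19 in Het (SD, n = 6 and 6) and was not called (adjusted p = 0.348).

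In the PFC, sex went largely with the identifier prefix. The prefix of WT M03, WT M07, Het M05 and Het M08 held only males. All females except WT F04 shared another with WT M11 and Het M09. Counts by sex therefore cannot be fully told apart from the prefix. The count of 52 was 2 without the sex covariate, 19 with the identifier prefix as a block, 17 with the removed direction as a covariate, 0 without the trend and robust settings, 340 in females and 2 in males. It was 3 without WT F04, WT M11, Het F04 or Het F07, 5 without WT F10, 7 without Het F02, 31 without WT F06, 97 without WT M07, 123 without Het M05 and 127 without Het M09; the split of 23 and 29 became 20 and 51 with median centring, 20 and 44 with quantile normalisation and 25 and 19 after correction for GC content and length. After the GC and length correction, 17 of the 23 higher genes and 14 of the 29 lower genes were still called. Of the 22 named genes called, Myt1l and Syt3 stayed called in the set of alternatives used for named genes. That set leaves out changed covariates and eBayes settings, and without the trend and robust settings neither was called. With all libraries kept, 7 of the 22 lost the call under another pseudocount, filter, scaling or the GC correction, 6 of them under the GC correction. The 7 were Dyrk1b, Grin1, Hbb-bt, Serinc2, Sox11, Stox2 and Zfp575.

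**Figure D4:**
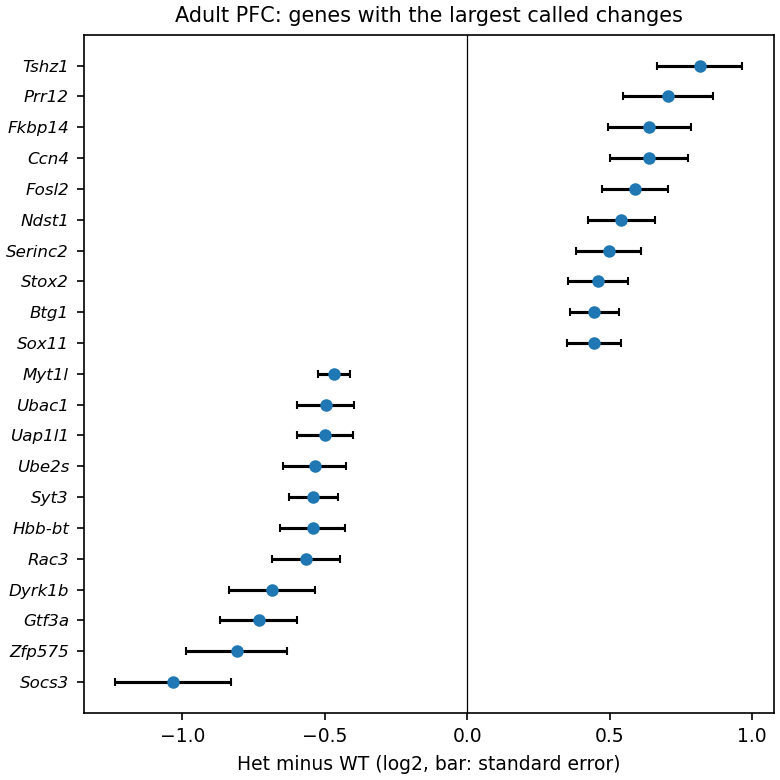
Log2 change between Het and WT in adult PFC (x axis, bars give the standard error) of Myt1l and the 20 genes with the largest called changes by the naming rule (y axis). Tshz1 lies highest at 0.82, Socs3 lowest at -1.03 and Myt1l at -0.47.

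No gene was called for an interaction of genotype and sex in the PFC (limma, lowest adjusted p = 0.237), nor by voom, and 1092 genes had an unadjusted p under 0.05. As sex went largely with the identifier prefix, differences between the sexes cannot be fully told apart from the prefix. The difference between Het and WT was more positive in males than in females for the astrocyte list (median 0.27, camera adjusted p = 1.2e-04) and the microglial (0.19, adjusted p = 0.0157) and oligodendrocyte (0.17, adjusted p = 0.0369) lists. It was more negative in males for the immediate early (-0.28, adjusted p = 0.00432), ion channel (-0.16, adjusted p = 0.0102), upper-layer (-0.20, adjusted p = 0.0253) and postsynaptic (-0.08, adjusted p = 0.0369) lists. Single male libraries stood apart in the direction of 2 of these differences: the immediate early list was low in Het M09 and the microglial list low in WT M07. With an estimated correlation none of the 7 passed, the adjusted p being 0.511 for the astrocyte and upper-layer lists and 0.612 for the other 5. Adjusted over the list alone, 6 of 12 astrocyte genes passed (a more positive difference between Het and WT in males), 1 of 10 upper-layer genes and none in the other 5 lists. Correction for GC content and length gave 1 call, Atf4, a transcription factor of the stress response, chosen after its value was seen (-0.81, SE 0.12, adjusted p = 0.0158, against -0.74 and 0.237 without the correction). With the same correction fewer lists passed by camera, as counted further below. Leaving out WT F06 gave 13 called genes and leaving out Het F07 gave 2.

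Fold changes of Het against WT at E14.5 and in the PFC were not related beyond chance. Across 11581 genes tested at both ages, Pearson's r was 0.0370 and Spearman's rho 0.0716, and 100 permutations of the PFC genotypes gave r between -0.195 and 0.140 (two-sided permutation p = 0.802). Among called genes, Btg1 was higher in Het at both ages, where independent lists would share 0.683 genes, and no gene was lower at both. Hom embryos and PFC Het shared 4 higher genes, Btg1, Fosl2, Nrep and Zfp385b (0.777 for independent lists), and 1 lower gene, Myt1l (1.05 for independent lists). Nrep was outside the naming rule and was listed after the overlap was seen.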

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

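The covariance, GC, simulated RUVr, Het F02 and ventral tissue tests were chosen after the results they bear on had been seen, whereas the splits and the relation of the score to Myt1l were set beforehand. Each comparison was set against 100 splits of the same libraries into groups of the same sizes, the real one included. Only 1 split gave as many called genes for Hom against WT (944 real, 16 the highest other), 1 for Het against WT (724, 446), 1 for the slope over copies (997, 30) and 1 for the PFC comparison (52, 14), but this does not exclude chance. The directions that the RUVr step removed held almost none of the genotype (at most 2.35e-05 of their length squared at E14.5 and 9.27e-05 in the PFC, against 0.133 and 0.0909 for random directions), as they would if that step was fitted with the real genotypes, which favours the real split. The criterion set beforehand, under 5 in 100 splits, did not allow for this. For Hom against Het, 8 splits gave 1 call or more (highest other 42), and for the interaction with sex 100 gave 0 or more (highest other 118). As many called lists came from 32 splits for Hom against WT (6 real, 11 the highest other), 22 for Het against WT (7, 13), 86 for Hom against Het (2, 11), 33 for the PFC comparison (4, 8) and 10 for the interaction with sex (7, 8), so chance is not excluded for any list count.

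Genes called in both Het and Hom embryos, such as the lower Mcm genes, were weighed against 3 technical explanations. For a GC or length trend, the medians give only what was left once the fitted trend was removed. The median of the 187 genes higher in both moved from 0.44 to 0.37 in Hom (median SE 0.11 and 0.10) and from 0.41 to 0.31 in Het (0.10 and 0.09). That of the 256 lower genes moved from -0.38 to -0.34 in Hom (0.08 and 0.08) and from -0.34 to -0.32 in Het (0.08 and 0.07). Of these genes, 60 of the 187 and 184 of the 256 were still called in both; the other calls of higher genes ended as the median change shrank by a larger share than its SE, so part of the higher genes' change may follow the trend. A first criterion, replaced after its values were seen, was the share of each genotype's calls that stayed: 50.1% of the higher and 77.5% of the lower genes in Hom, and 28.9% and 73.1% in Het. Over all genes tested, the trend held 6.9% of the variance of the fold changes in Hom and 10.7% in Het. As the genes were picked by the uncorrected test, medians away from 0 were likely to remain. The values therefore show how much of the change the fitted trend held and do not decide whether it was the whole cause. Shared WT libraries stay open. With none shared, the covariance of fold changes averaged 0.0304 over 20 divisions (lowest 0.0243), and 0 of 100 simulated unchanged groups reached that mean (highest 0.0245), or 1 of 100 in the first version (highest 0.0335). However, an RUVr step fitted with the genotypes leaves the WT libraries with a common error that dividing them does not part: without a genotype effect, 3 of 20 simulations with loadings of 0.2 (SD, log2) and 10 of 20 with 0.4 reached 0.0304 after such a step, against 1 and 5 before it and 0 with no loadings. Criteria for this test were replaced after their values were seen, the first being a covariance above 0 and the next one above the highest unchanged group. Also open is unwanted variation parallel to genotype that the RUVr step could bring in: 20 simulations without a genotype effect and with loadings of 0.2 (SD, log2) gave a median of 1251 calls for Hom against WT after such a step, and 0 with no loadings, and 8 of the 20 gave as many calls as observed in both WT comparisons (3 of these with as few calls between Hom and Het). With loadings of 0.4, 15 of 20 did, none of them with as few between Hom and Het. For the PFC comparison such simulations gave a median of 610.5 calls with loadings of 0.2 (highest 5498) and 0 with no loadings, against 52 observed. A shared effect of Myt1l loss at E14.5 therefore remains a hypothesis beside these.

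The library labelled Het F02 had Myt1l at 59.5 CPM, within the WT range and above the WT mean. Het M07 (48.9 CPM) and Het F07 (45.95 CPM) also lay within that range, below the mean. A score set the mean of the WT libraries used at 0 and that of the Hom libraries used at 1, with each library scored without itself. The score placed this library at 0.662, above the WT libraries (mean 0.136, -0.174 to 0.353). That value lay within the other Het libraries (0.417 to 0.959) and also within the Hom libraries (mean 0.707, 0.597 to 0.797). Het libraries were scored over 1378 genes and WT and Hom libraries over 782 to 1315, so their scores are not on quite the same footing. A WT library under a Het label stays open all the same. An RUVr step fitted with the labels could draw libraries toward their labelled group, and this was not tested here. In Myt1l, the gap of the library labelled Het F02 to the next Het library was 0.367 of the group's range, under Dixon's limit. Spread among Het libraries may thus account for its Myt1l level. Across the 6 Het libraries the score was not shown to follow Myt1l (Pearson's r 0.0292, exact permutation p = 0.936; Spearman's rho -0.2, exact permutation p = 0.714; both 0.936 after Benjamini-Hochberg adjustment over 2 relations; r 0.189 without Het F02 and Het M11). The criterion set beforehand took a p of 0.05 or more as an exclusion, which was wrong, since with 6 libraries a missed threshold excludes nothing.

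In Hom embryos 2 of 12 GABAergic interneuron genes were called higher, the list did not pass with an estimated correlation (adjusted p = 0.753), and ventral markers stood high in some of the same libraries. With the mean of the ventral markers as a covariate, the change of the GABAergic list mean was 0.194 (SE 0.266), against 0.436 (SE 0.229) without it. Within groups both means had r 0.426 and rho 0.365 (permutation p = 0.101 for r, 100000 resamples), and r 0.141 without Het M07 and Hom F01. Ventral tissue in the dissected cortex may thus account for part of the list's change, and it cannot be told apart from an effect of genotype, because neither change exceeded 2 of its standard errors and the Hom group holds 4 libraries.

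Among 447 groups of libraries tested for 1 library far from the others, 19 had one, and chance gives about 1 in 20. In Het embryos, with the gap given as a share of the group's range, these were Numb low in Het F07 (0.685), Ppp1r1b low in Het M11 (0.757), the Wnt list low in Het M01 (0.669), the immediate early list high in the library labelled Het F02 (0.712), the presynaptic list low in Het M11 (0.738) and the ventral list high in Het M07 (0.701). In Hom they were Gramd2 low (0.835), Snx7 high (0.844), Tubb3 low (0.892) and Vsir low (0.874) in Hom F09. In E14.5 WT they were Ccnb1 high (0.645) and Nefm low (0.671) in WT F04 and Thsd1 low in WT F06 (0.731). In the PFC they were the immediate early list low in Het M09 (0.631), Nrep low (0.692) and St18 high (0.671) in WT M03, the GABAergic list high in WT F06 (0.652), the deep-layer list high in WT F04 (0.651) and the microglial list low in WT M07 (0.739).

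By camera on the interaction of genotype and sex in the PFC with the preset correlation, lists passed for astrocyte (adjusted p = 1.2e-04), immediate early (0.00432), ion channel (0.0102), microglial (0.0157), upper-layer (0.0253), oligodendrocyte (0.0369) and postsynaptic (0.0369) genes. None of them passed with an estimated correlation. Sex went largely with the identifier prefix there, so an effect that differs by sex cannot be fully told apart from one that differs by prefix. Each Het library of 1 age lay on the opposite side of its WT mean from each Het library of the other age for C1qc (-0.28 in PFC, 0.32 at E14.5), Marcksl1 (-0.37 and 0.33) and Serinc2 (0.50 and -0.21); these differences between ages were not tested.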

How the results depend on the processing

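Voom, GC correction, exchanged sex labels, libraries left out for named genes, fits of 1 sex in the PFC and the combined settings were chosen after the data had been examined; edgeR was not run. No paired analysis was possible because the labels give each library its own animal identifier and pair no libraries. No result changed direction while called, and the causes of the changes below were not tested, except that a threshold of 0.1 admits more genes by construction. With the removed RUVr directions as covariates, the counts of called genes were 511 (Hom against WT), 335 (Het against WT), 0 (Hom against Het), 510 (slope) and 17 (PFC); with GC correction as well, 439, 193, 0, 460 and 13, and 1 for the interaction with sex. The fit with these covariates does not correct for unwanted variation parallel to genotype. In simulations without a genotype effect (loadings of 0.2) it gave medians of 883 (Hom against WT), 643 (Het against WT) and 439.5 (PFC) calls. Without trend and robust settings the real counts were 468, 225, 0, 484 and 0. With a threshold of 0.1 they were 1627, 1348, 1719 (slope) and 206 (PFC). Het against WT gave 379 with only these genotypes and 450 in libraries labelled female (Het F10, with Y-linked transcripts, included). Hom against Het gave 0 with the identifier prefix as a block, with only these genotypes, in libraries labelled female, with voom and with GC correction. The PFC comparison gave 2 without the sex covariate, 19 with the prefix as a block (16 shared with the 52), 3 with both, 340 in females (49 shared) and 2 in males (1 shared). Sex went largely with the prefix, so the counts by sex cannot be fully told apart from it. The interaction gave 1 with GC correction. Leaving out 1 library gave 489 to 1099 (Hom), 131 to 1177 (Het), 0 to 1 (Hom against Het), 455 to 1109 (slope), 3 to 127 (PFC) and 0 to 13 (interaction). Without the library labelled Het F02 the Hom count was 897 and the slope 916; with exchanged sex labels Hom gave 1032 and Het 937.

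Called lists numbered 0 in each comparison with an estimated correlation. By fry's directional test, which asks whether a list moves in 1 direction without comparing it with other genes, they numbered 1 (Hom), 3 (Het), 0 (Hom against Het), 0 (PFC) and 0 (interaction). Fry's mixed test, for changes in either direction, was not counted. In Hom its adjusted p was 0.00192 for the S phase list and 0.00747 for the radial glia list, against directional values of 0.109 and 0.565. A filter of 5 CPM gave 3 for Hom, the removed directions 4 for Hom against Het and GC correction 3 for the interaction. Leaving out 1 library gave 1 to 8 (Hom), 4 to 7 (Het), 2 to 5 (Hom against Het), 2 to 6 (PFC) and 3 to 7 (interaction). The r between Het and Hom was 0.778 with a filter of 5 CPM and 0.838 for genes with a mean of 10 CPM or more, and 0.638 to 0.711 with 1 library left out; that between the ages was -0.0036 to 0.0681. Of called named genes, 31 of 44 (Hom), 33 of 42 (Het) and 20 of 22 (PFC) were not called without at least 1 library. Depth is unknown, so its limit on low genes was not measured.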

Other observations

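Glycolysis genes, a list chosen after their falls had been seen, were lower in both mutant genotypes at E14.5. Of 17 entries, 13 were lower in Hom (median -0.39; camera p = 6.26e-19, and p = 0.00329 with an estimated correlation) and 10 in Het (median -0.27; p = 6e-14, and p = 0.00941 with an estimated correlation), with none higher. Pkm, a pyruvate kinase, changed by -0.51 in Hom and -0.46 in Het, and Ldha, a lactate dehydrogenase, by -0.41 and -0.27. Tpi1 changed by -0.33 and -0.25 and Pgk1 by -0.29 and -0.21. With correction for GC content and length, 12 and 9 entries were lower. In adult PFC none of 16 entries was called by limma, and the list was lower by camera (median -0.05; p = 0.000784, and p = 0.223 with an estimated correlation), with a median of -0.02 after correction for GC content and length (p = 0.0121 and 0.304). As the genes were picked from these data, the p-values describe the pattern and do not test it independently.

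Cytosolic ribosomal protein genes, also chosen afterwards, had 17 of 79 higher and none lower in Het embryos (camera p = 5.05e-11, and p = 0.233 with an estimated correlation). After correction for GC content and length, 6 of the 79 were higher and 3 lower. The median of the 79 genes fell from 0.145 to 0.00357 with the correction (camera p = 0.0662, and p = 0.681 with an estimated correlation). In Hom, 5 were higher and 3 lower, and the list was lower in Hom than in Het with no gene called (median -0.092; camera p = 4.71e-11, and p = 0.232 with an estimated correlation; median -0.0267 and p = 0.00243 after the correction). In PFC Het it was higher with no gene called (camera p = 5.09e-08, and p = 0.383 with an estimated correlation; 1.77e-07 and 0.331 after correction for GC content and length).

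The library labelled Het F10 carried Y-linked transcripts (Ddx3y 21.6, Eif2s3y 18.7, Kdm5d 10.5 and Uty 7.91 CPM), and in the library labelled Het M11 all 4 were at 0. Both belong to the same genotype, so an exchange of their sex labels would leave the groups as they are. Tested for calls between the identifier prefixes, the E14.5 libraries gave 0 calls (11 against 5 libraries) and the PFC libraries 11 (4 against 7 libraries, leaving out the prefix with 1 library).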
